A study of Mus musculus with 6 samples.

How the data were processed

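The series holds 6 Affymetrix MOE430 2.0 arrays of mouse bone marrow cells, 3 transfected with a miR-142-3p mimic and 3 with a control oligonucleotide, all then cultured with GM-CSF and IL-6. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin during 16 h of in vitro transcription. Arrays were placed in the mimic or the control group by the treatment that the labels state, and they are numbered as in their titles.

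The deposited table gives 1 value per probe set and array on a log2 scale. RMA and affy are named in the submitters' processing notes, with no version, order or role, and the probe set definitions and any filter are not given in the sources used here. The base of the logarithm was taken from the values. Between the bacterial spike-in probe sets the values rose by 0.784 to 0.904 per log2 step of the manufacturer's standard concentrations, and the highest deposited value, 12.3, exceeds the natural log of the largest 16-bit intensity, 11.1. The centring and the floor of the deposited values are not stated. Values start slightly below 0, at -0.39, and 52.6% of them lie below 1, lower than is usual for RMA, so a log2 value of 6, the lowest level asked of a named gene, lies at the 87.3rd percentile of the gene means. Column medians were 0.92, 0.84 and 0.88 in control arrays 1, 2 and 3 and 0.89, 0.88 and 0.91 in mimic arrays 1, 2 and 3. The values were used as deposited, with no further normalisation. No 2 arrays held the same values, and Pearson correlations between arrays ran from 0.982 to 0.996 across probe sets.

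Of 45101 probe sets, 64 are Affymetrix controls, 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 have none listed. Symbols were updated through their gene identifiers to current RefSeq names, which matched 34741 of the 34945, and the other 204 kept the annotation's symbol. Each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays among those with 1 symbol, and 9010 genes had more than 1 to choose from. Probe sets with several symbols or none were left out of gene tests. Genomic coordinates, 3′ UTR sequences and microRNA seed sites were not used here, so the planned comparison of genes with and without a seed site was not made.

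The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate, all 6 arrays), and p-values were adjusted by Benjamini-Hochberg over the 18193 genes with a threshold of 0.05. The median SE of a log2 fold change was 0.12. Before the data were examined, 26 gene lists were fixed from general knowledge of marrow cell types, MDSC functions, cytokine signalling, stress and metabolism and of published miR-142-3p targets, with 436 entries of which 389 were measured. Il6st and Cebpb belong to both the target list and the IL-6 list, and Il6 to both the target and the NF-kB list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists, and members were also adjusted over the list alone. Camera with an estimated correlation and fry were the alternatives. The control probe sets for actin, Gapdh and the spike-ins were compared by exact two-sided permutation, where the smallest possible p is 0.1.

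The rule for named genes was also fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among genes at an adjusted p under 0.05 whose groups do not overlap and whose higher group has a mean log2 of at least 6, passing over unnamed gene models. It adds from each list up to 3 members with the largest change at an adjusted p under 0.05, or otherwise the 1 member with the largest change, and 10 genes chosen for their role in MDSCs and macrophages, of which 8 were measured. The remainder of the 10 are not reported here.

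The method was tested on simulated data with the real genes and spreads, 200 changed genes per draw and 10 draws. The changed genes and the lists were drawn only from genes with a mean log2 of at least 3. The simulation had no floor and gave all arrays the same spread, so recovery in dim genes was not measured. For the mimic against control comparison of 18193 genes it recovered 29.0% of the genes changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 100% of those changed by 2, and 6.41% of calls were false. Camera called 50 of 50 simulated lists of 20 genes shifted by 0.7 and 1 of 50 unshifted lists. The simulated genes varied independently of each other. In the real data the estimated correlation was 0.70 in the interferon list, 0.64 in the class II list and 0.58 in the neutrophil precursor list. The share of unshifted lists called therefore does not carry over to the real lists. Alternatives tried were the replicate number as a block, each array left out, filters on dim genes, other choices of probe set, other variance models and array weights, centring and quantile normalisation, and a minimum fold of 1.2. Added after seeing the data were lower filters on dim genes, control array 1 and mimic array 3 left out together, and the mean spike-in level as a covariate.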

Results

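Bone marrow cells of C57BL/6 mice received either a mimic of miR-142-3p, a microRNA abundant in blood cells, or a control oligonucleotide, both at 100 nM. The cytokines GM-CSF and IL-6 were added 5 h later and left for 4 days, a culture in which marrow yields myeloid-derived suppressor cells (MDSCs), immature myeloid cells that restrain T cells. RNA was measured on 6 Affymetrix MOE430 2.0 arrays, 3 for the mimic and 3 for the control, and 18193 genes were compared, each through 1 probe set. Levels below are deposited log2 values given as mean ± SD over 3 arrays, and fold changes are mimic against control with ± SE. The labels do not say that the arrays of a group come from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

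The comparison asked which transcripts differ when miR-142-3p is raised while the MDSCs form. With the mimic, genes of the interferon response were higher, as were genes of neutrophil precursors. Genes of dendritic cells, of MHC class II antigen presentation and of NF-kB-driven inflammation were lower. Each of these lists passed limma's camera at its preset correlation and none with an estimated one (adjusted p = 0.161 for each), and of the 11 neutrophil precursor genes 2 passed over all genes tested, the granule protease genes Ctsg and Elane. The dendritic cell chemokine gene Ccl17 was 23.4-fold lower (log2 fold change -4.55 ± 0.42, adjusted p = 0.00673 by limma), and Ifit1bl1, of the interferon-induced Ifit family, was 31.9-fold higher (log2 fold change 5.00 ± 0.74, adjusted p = 0.0181). Without control array 1 the latter was 16.1-fold higher, and without control array 3 it was 51.7-fold higher. In all, 503 genes passed an adjusted p of 0.05, 213 of them higher and 290 lower with the mimic, and 169 of the 503 differed at least 2-fold (70 higher, 99 lower). In each of the 503 the 3 mimic arrays lay outside the range of the 3 control arrays. This separation held for 4037 genes in all, or 22.2% of those tested, against 10% by chance. With limma, 0 genes passed when control array 2, mimic array 1 or mimic array 3 was left out (2564, 2343 and 2746 genes at an unadjusted p under 0.05). Without mimic array 2, 65 passed. All 503 kept their direction in each of these fits, but their separation fixes this in advance, so it adds no support. A further round of quantile normalisation gave 322 genes higher and 290 lower, and a fit with the spike-in level of each array as a covariate, chosen after seeing the data, gave 1135 higher and 891 lower.

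Genes of the type I interferon response, which cells switch on against viruses, were higher with the mimic. Of 23 measured members 16 rose, 0 fell and 7 did not pass, and 20 rose when adjusted over the list alone. The list's median log2 fold change was 0.98 (adjusted p = 4.27e-19 by limma's camera, adjusted p = 0.161 with an estimated correlation). Rsad2 (Entrez gene 58185), which encodes the antiviral protein viperin, rose from 6.84 ± 0.89 to 9.17 ± 0.05 (SD, n = 3), a 5.03-fold difference (log2 fold change 2.33 ± 0.38, adjusted p = 0.0229 by limma). The chemokine gene Cxcl10 rose 5.06-fold from 5.25 ± 0.96 to 7.59 ± 0.14, Ifit2 rose 5.04-fold and Ifit3 rose 4.40-fold. In a fit of all probe sets, Cxcl10 and Ifit2 did not pass (adjusted p = 0.0594 and 0.062 by limma). These probe sets of Rsad2 and Ifit3 did (adjusted p = 0.0483 and 0.0309). With all probe sets of a gene averaged, the log2 fold change of Rsad2 was 1.67 and did not pass (adjusted p = 0.176 by limma). Outside the list, Ifit1bl1 (Entrez gene 667373) rose from 3.30 ± 1.76 to 8.30 ± 0.15, with a log2 fold change of 4.01 without control array 1 and of 5.69 without control array 3. The interferon-inducible GTPase gene Iigp1 rose 7.80-fold, from 3.54 ± 1.0 to 6.50 ± 0.10, and Cmpk2, a mitochondrial nucleotide kinase gene induced by interferon, rose 4.30-fold. The control arrays were uneven in this group. Relative to the control mean, the median of the list was -0.33, 0.10 and 0.27 in control arrays 1, 2 and 3, and 0.96, 1.01 and 0.94 in mimic arrays 1, 2 and 3. Without control array 1, 12 members rose and 1 fell. The latter, Eif2ak2, which encodes the double-stranded RNA sensor kinase PKR, was chosen after its values were seen. Its log2 fold change was -1.80 ± 0.23 there (adjusted p = 0.0262 by limma), against -1.02 ± 0.59 with all arrays (adjusted p = 0.443). Without mimic array 2, 2 members rose, and 0 did without control array 2, mimic array 1 or mimic array 3, while camera kept the list past its threshold in each of these fits.

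**Figure D1:**
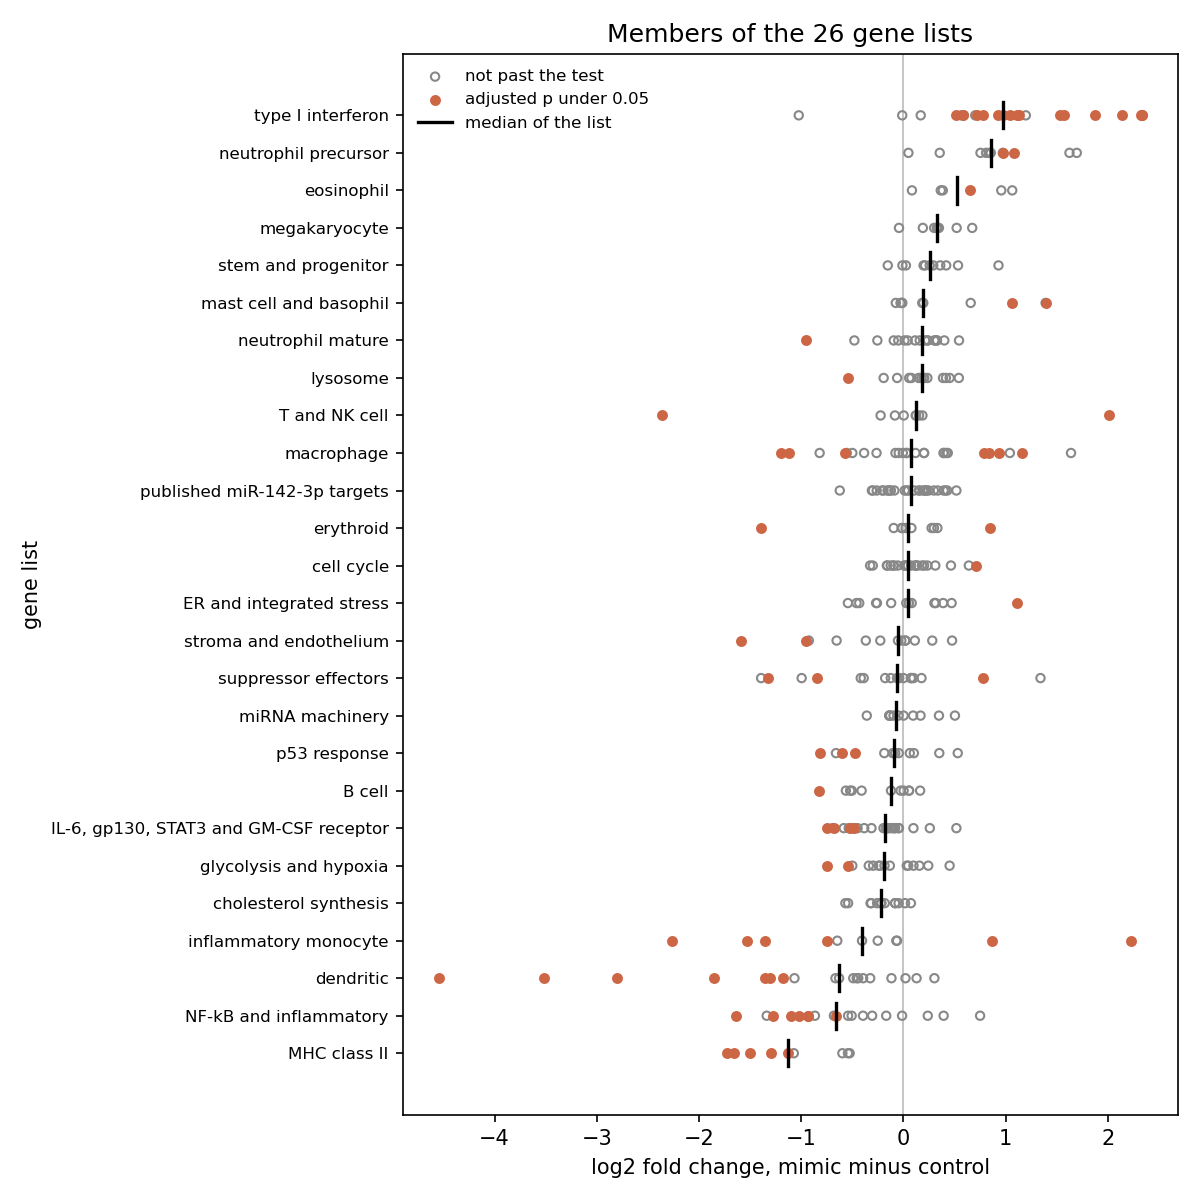
Each point is 1 measured member of the 26 gene lists, placed by its log2 fold change (mimic minus control, horizontal axis), with filled points for genes at an adjusted p under 0.05 and a black bar at the median of each list. The interferon list has its median at 0.98 and the MHC class II list at -1.13, while the median of the published miR-142-3p targets is 0.08 and none of their points is filled.

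Dendritic cell genes were lower with the mimic. Of 19 measured members 7 fell and 0 rose, and 13 fell when adjusted over the list alone (median log2 fold change -0.63, adjusted p = 1.06e-10 by limma's camera, adjusted p = 0.161 with an estimated correlation). Most members were dim, and only 2 had a mean log2 of at least 6. With genes below a mean log2 of 5 left out, 5 members remained, of which 3 fell (median -1.31). With genes below 7 left out, too few remained to test the list. Ccl17 (Entrez gene 20295) fell from 7.23 ± 1.0 to 2.68 ± 0.04 (SD, n = 3). Ccl22, whose product attracts T cells through the same receptor as that of Ccl17, was 11.5-fold lower (log2 fold change -3.52 ± 0.47). Itgax (Entrez gene 16411), which encodes the dendritic cell integrin CD11c, fell from 7.14 ± 0.63 to 4.34 ± 0.08, a 6.96-fold difference. All 9 measured genes of MHC class II presentation had a lower mean with the mimic. Of these 5 fell over all genes tested and 9 fell when adjusted over the list alone (median log2 fold change -1.13, adjusted p = 1.16e-09 by limma's camera, adjusted p = 0.161 with an estimated correlation). Cd74, the invariant chain gene, fell from 10.24 ± 0.51 to 8.58 ± 0.03 and was 3.16-fold lower. The class II chain genes H2-Ab1 and H2-Eb1 were 3.31-fold and 2.82-fold lower. In both lists control array 1 lay above the other controls, at 0.34 against -0.13 and -0.22 for the dendritic list and at 0.44 against -0.11 and -0.34 for the class II list, relative to the control mean. Without control array 1, 7 dendritic and 6 class II genes fell. Without mimic array 2 these numbers were 4 and 0, with list medians of -0.56 and -1.22.

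**Figure D2:**
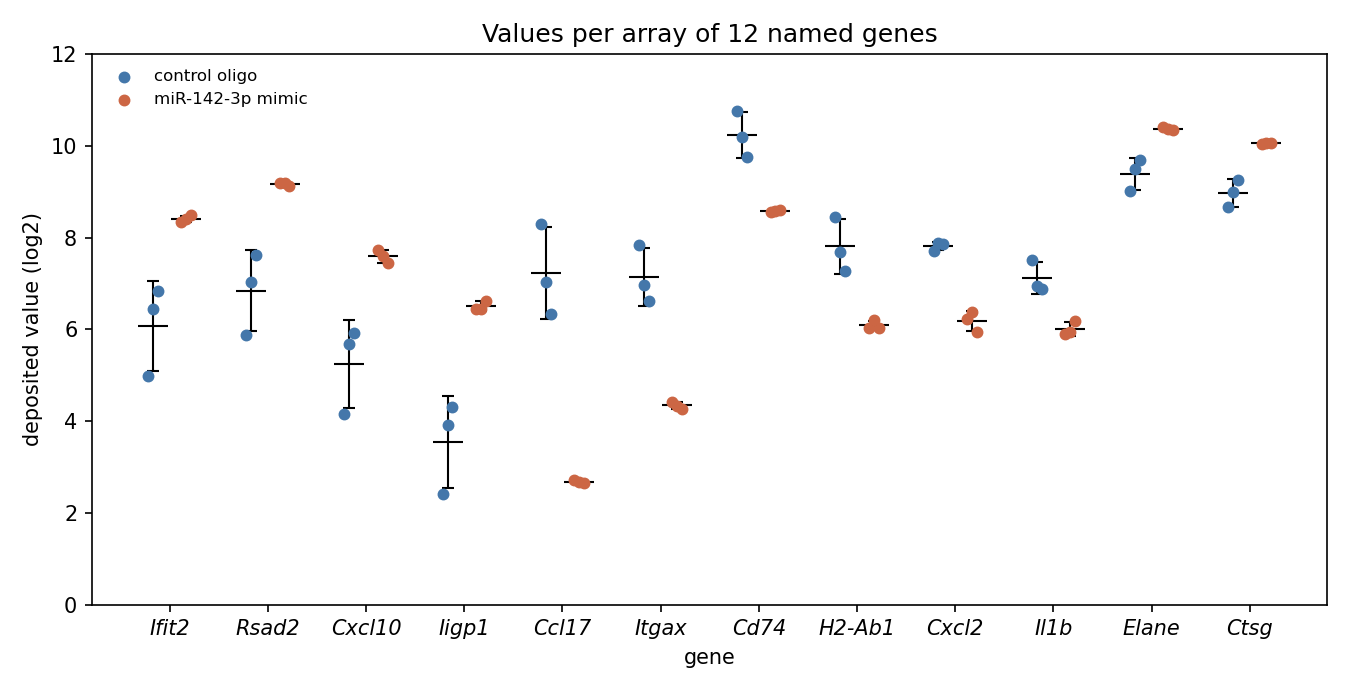
Deposited log2 values (vertical axis) of 12 named genes on each of the 6 arrays, 3 control (blue) and 3 mimic (orange), with horizontal bars at the group means and error bars of 1 SD. For each gene the 3 mimic arrays lie apart from the 3 control arrays, as for Ccl17 at 2.68 ± 0.04 against 7.23 ± 1.0. The 12 were picked from genes past the test, all of which have groups that do not overlap, so this separation follows from the choice.

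Inflammatory genes driven by NF-kB were lower with the mimic. Of 19 measured members 7 fell and 0 rose, and adjusted over the list alone 12 fell and 1 rose (median log2 fold change -0.66, adjusted p = 2.99e-08 by limma's camera, adjusted p = 0.161 with an estimated correlation). The neutrophil-attracting chemokine gene Cxcl2 (Entrez gene 20310) fell from 7.82 ± 0.09 to 6.18 ± 0.23 (SD, n = 3), or 3.12-fold. Relb, which encodes a subunit of NF-kB itself, was 2.43-fold lower and the cytokine gene Il1b was 2.14-fold lower. Other falls among the named genes were those of Ptx3, a secreted pattern recognition protein (log2 fold change -2.27 ± 0.21), Plet1 (-2.82 ± 0.34), Mfge8, whose product bridges phagocytes to dying cells (-2.23 ± 0.39), and Pdpn, which encodes podoplanin (-2.01 ± 0.19). Of 24 measured genes of IL-6, gp130, STAT3 and GM-CSF receptor signalling, 4 fell and 0 rose, and 9 fell and 1 rose when adjusted over the list alone (median log2 fold change -0.18, adjusted p = 1.45e-05 by limma's camera, adjusted p = 0.161 with an estimated correlation). The 4 were the kinase gene Jak1 (-0.75 ± 0.14), the GM-CSF receptor genes Csf2rb (-0.53 ± 0.11) and Csf2ra (-0.49 ± 0.10), and Csf2rb2 (-0.68 ± 0.11), which encodes a related beta chain of the IL-3 receptor. Csf2ra was chosen after its values were seen. A second probe set of Jak1 of similar brightness, at 5.98 in control and 5.94 with the mimic, had a log2 fold change of -0.04 (adjusted p = 0.919 by limma). With any single array left out at most 1 gene of this list fell, and 2 NF-kB genes fell without mimic array 2.

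Genes of neutrophil precursors were higher with the mimic in all 11 measured members. Of these 2 rose over all genes tested, and 10 rose when adjusted over the list alone (median log2 fold change 0.86, adjusted p = 4.07e-09 by limma's camera, adjusted p = 0.161 with an estimated correlation). Ctsg, the gene of cathepsin G, rose from 8.97 ± 0.30 to 10.05 ± 0.01 (SD, n = 3), and Elane, the gene of neutrophil elastase, rose from 9.39 ± 0.35 to 10.37 ± 0.03. Control array 1 was again apart, with a list median of -0.46 relative to the control mean against 0.10 and 0.34 in the other controls. Without control array 1, 6 of these genes rose, without control array 3 5 rose, and without any other single array 0 rose. Among 18 genes of mature neutrophils 1 fell and 0 rose, and 2 rose and 2 fell when adjusted over the list alone (median log2 fold change 0.19, adjusted p = 0.133). The gene that fell was Mmp8, a collagenase of neutrophil granules, at 9.25 ± 0.19 in control and 8.30 ± 0.17 with the mimic. Csf3r, the G-CSF receptor gene, had a log2 fold change of -0.25 ± 0.11 (adjusted p = 0.282 by limma).

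The IL-6 receptor subunit gp130, encoded by Il6st, and the transcription factor gene Cebpb were in a list of published miR-142-3p targets, of which 28 were measured. None of the 28 passed the test over all genes, and Il6st was higher when adjusted over the list alone (1 rose, 0 fell). Over all genes, Il6st passed upward without control array 1 (adjusted p = 0.0497 by limma), with a trended robust variance, with arrays centred on their medians and with repeated quantile normalisation. Il6st and Bclaf1 passed upward with array weights, and Il6st, Apc, Il6 and Cpeb2 passed upward with the spike-in covariate, while 0 fell in each of these fits. The list as a whole had a median log2 fold change of 0.08 (adjusted p = 0.491 by limma's camera, adjusted p = 0.778 with an estimated correlation), with 17 members higher and 11 lower in their means. For 23 of the 28 the 95% interval excluded a fall of 0.5 on the log2 scale. The list median was 0.04 over the 25 members with a mean log2 of at least 3, -0.12 over the 9 with at least 5 and -0.17 over the 4 with at least 7. With only genes of these levels tested, Il6st passed upward at 3 (adjusted p = 0.0267 by limma), Bclaf1 passed upward at 5 (0.41 ± 0.10, adjusted p = 0.033) and Rac1 passed downward at 5 and 7 (-0.31 ± 0.08, adjusted p = 0.0472 and 0.0317). Apc, Il6, Cpeb2, Bclaf1 and Rac1 were chosen after their values were seen. Il6st (Entrez gene 16195) stood at 4.61 ± 0.14 in control and 5.13 ± 0.11 with the mimic (SD, n = 3), a log2 fold change of 0.52 ± 0.11 (adjusted p = 0.0526 by limma). Its 3 dimmer probe sets had log2 fold changes of -0.001, -0.24 and -0.39, so the probe sets disagreed in sign. The log2 fold change of Cebpb was -0.19 ± 0.11 (adjusted p = 0.454), and that of Gnaq, the largest in size among the targets, was -0.62 ± 0.45 (adjusted p = 0.563). Among 12 genes of the microRNA machinery 0 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of -0.07 and a mean of 0.01, which differ in sign (adjusted p = 0.912 by limma's camera). Tnrc6b had the largest change there, 0.50 ± 0.21 (adjusted p = 0.275).

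Macrophage genes went both ways. Of 26 measured members 4 rose and 3 fell, and adjusted over the list alone 8 rose and 7 fell (median log2 fold change 0.08, adjusted p = 0.44 by limma's camera). Itgam, which encodes CD11b, was 2.29-fold lower, at 6.60 ± 0.33 in control and 5.41 ± 0.15 with the mimic (SD, n = 3). The endotoxin co-receptor gene Cd14 was 2.17-fold lower, and Csf1r, the M-CSF receptor gene, was 1.48-fold lower. Cd5l was 2.23-fold higher but dim, at 1.37 ± 0.31 and 2.53 ± 0.04. Adgre1, a surface receptor gene used as a macrophage marker, had a log2 fold change of -0.38 ± 0.11 (adjusted p = 0.113 by limma). Of 11 inflammatory monocyte genes 4 fell and 2 rose, and 6 fell and 2 rose when adjusted over the list alone (median log2 fold change -0.40, adjusted p = 0.00206 by limma's camera, adjusted p = 0.161 with an estimated correlation). The fibronectin gene Fn1 (-2.27 ± 0.30) and S100a4 (-1.53 ± 0.21) fell, while Ms4a4c, a tetraspan membrane protein gene, rose 4.68-fold. With genes of a mean log2 below 7 left out the list's direction turned (adjusted p = 0.414).

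Genes for the suppressive functions of MDSCs also went both ways. Of 17 measured members 1 rose and 2 fell, and 2 rose and 5 fell when adjusted over the list alone (median log2 fold change -0.06, adjusted p = 0.0733 by limma's camera, adjusted p = 0.223 with an estimated correlation). The alternative test fry, which asks whether a list's genes move on balance 1 way, did pass the list downward (adjusted p = 4.44e-04 by limma's fry). Cd274, which encodes the T cell inhibitor PD-L1, rose from 6.21 ± 0.06 to 6.99 ± 0.13 (SD, n = 3), or 1.72-fold. The cystine transporter gene Slc7a11 and the arginine transporter gene Slc7a2 fell, with log2 fold changes of -1.33 ± 0.18 and -0.85 ± 0.11. Arg1, the arginase gene, stood at 3.31 ± 0.98 in control and 4.65 ± 0.12 with the mimic and did not pass (log2 fold change 1.34 ± 0.42, adjusted p = 0.148 by limma). With control array 1 and mimic array 3 both left out, a fit chosen after seeing the data, this was 0.75 (adjusted p = 0.228). Nos2 lay at the floor of the arrays in both groups, at 0.62 ± 0.05 and 0.44 ± 0.08 (adjusted p = 0.38).

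Markers of other marrow cells were examined in the same way. Of 10 mast cell and basophil genes 2 rose and 0 fell, and 4 rose when adjusted over the list alone (adjusted p = 0.00561 by limma's camera, adjusted p = 0.161 with an estimated correlation). The 2 were the IgE receptor gene Fcer1a (1.40 ± 0.21) and the mast cell carboxypeptidase gene Cpa3 (1.06 ± 0.21). All 6 eosinophil genes had higher means, of which Prg3 passed (0.65 ± 0.12), and 5 rose when adjusted over the list alone (adjusted p = 4.1e-04 by limma's camera, adjusted p = 0.161 with an estimated correlation). No gene of 11 from stem and progenitor cells or of 8 from megakaryocytes passed over all genes, and 1 of each rose when adjusted over the list alone. Both lists passed camera upward (adjusted p = 0.00472 for each), with an adjusted p of 0.161 and 0.37 with an estimated correlation. Their largest changes were in Hoxa9 (0.93 ± 0.22, adjusted p = 0.0753) and Gp1bb (0.67 ± 0.18, adjusted p = 0.1). Of 11 B cell genes 1 fell, Ms4a1, which encodes CD20 (-0.82 ± 0.13), and 2 fell when adjusted over the list alone (adjusted p = 0.039 by limma's camera, adjusted p = 0.223 with an estimated correlation). In the T and NK cell list of 9 genes Thy1 was 5.14-fold lower and the granzyme gene Gzmb was 4.05-fold higher, and the same 2 passed when adjusted over the list alone. Gzmb was dim, at 1.72 ± 0.36 in control and 3.74 ± 0.28 with the mimic. The median of that list was 0.12 and its mean -0.01, which differ in sign (adjusted p = 0.662 by limma's camera). Of 10 erythroid genes the carbonic anhydrase gene Car2 fell (-1.39 ± 0.23) and the transcription factor gene Gata1 rose (0.85 ± 0.13), and the same 2 passed when adjusted over the list alone (list adjusted p = 0.253). Of 13 genes of stroma and endothelium 2 fell, decorin (Dcn, -1.58 ± 0.17) and the collagen gene Col1a2 (-0.95 ± 0.15), and 4 fell when adjusted over the list alone (adjusted p = 0.0319 by limma's camera, adjusted p = 0.322 with an estimated correlation).

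Metabolic and stress genes changed in few members. Of 15 glycolysis and hypoxia genes 2 fell, the glucose transporter gene Slc2a1 (-0.75 ± 0.13) and the triosephosphate isomerase gene Tpi1 (-0.54 ± 0.10), and 5 fell and 1 rose when adjusted over the list alone. Other probe sets of Tpi1, at 8.47 and 7.65 in control, had smaller log2 fold changes of -0.36 and -0.19. Neither passed in a fit of all probe sets (adjusted p = 0.128 and 0.459 by limma), where the first one stood at 0.0569. The list passed camera downward (adjusted p = 0.0291, adjusted p = 0.161 with an estimated correlation). Of 14 lysosomal genes the beta-glucuronidase gene Gusb fell (-0.54 ± 0.10), and 3 rose and 1 fell when adjusted over the list alone. The list as a whole passed upward with a median of 0.19 (adjusted p = 0.0357, adjusted p = 0.481 with an estimated correlation). Of 14 cholesterol synthesis genes none passed over all genes and 2 fell when adjusted over the list alone, and the list passed downward with a median of -0.22 (adjusted p = 0.00351, adjusted p = 0.24 with an estimated correlation). The largest change there was in Lss, the lanosterol synthase gene (-0.57 ± 0.12, adjusted p = 0.0593). Its other 2 probe sets lay near the floor of the arrays, at 0.70 and 0.68 in control, and without probe sets of type _x_at or _s_at its log2 fold change turned to 0.02 (adjusted p = 0.968 by limma). Among 12 targets of p53 the death receptor gene Fas (-0.81 ± 0.13), Zmat3 (-0.61 ± 0.12) and the cell cycle inhibitor gene Cdkn1a (-0.47 ± 0.09) fell, and 4 fell and 1 rose when adjusted over the list alone (list adjusted p = 0.0612). With any single array left out 0 of these genes fell, for Fas with adjusted p of 0.078 without control array 1 and 0.0589 without control array 3, and the latter fit called 1 rise, that of Perp (0.68 ± 0.11, adjusted p = 0.0356 by limma), chosen after its values were seen. Of 25 cell cycle genes 1 rose, over all genes and when adjusted over the list alone, the ribonucleotide reductase gene Rrm2 (0.71 ± 0.11), and 1 of its 3 probe sets had a log2 fold change of -0.03 (list adjusted p = 0.187). Of 14 genes of endoplasmic reticulum and integrated stress 1 rose, the transcription factor gene Ddit3 (1.11 ± 0.11), and 2 rose and 3 fell when adjusted over the list alone (list adjusted p = 0.987). For Fn1, Dcn and Ddit3 a second probe set at the floor of the arrays had the opposite sign, with log2 fold changes of 0.06, 0.12 and -0.05. With all probe sets averaged, Fn1 stood at -1.10, Dcn at -0.73, Ptx3 at -1.15 and Plet1 at -2.14, each past the test. Of the 26 lists, 16 passed camera with its preset correlation, 7 upward and 9 downward, and 0 passed with an estimated correlation. In the fit of all probe sets the chosen probe sets of further named genes did not pass either (adjusted p from 0.0545 to 0.0834 by limma). These were Cxcl10, Ifit2, Cmpk2, Ms4a4c, Mfge8, H2-Eb1, Elane, Jak1, Csf2rb, Cpa3, Prg3, Gusb, Slc2a1, Zmat3, Cdkn1a and Csf1r. Calls of further single genes were lost with 1 control array left out. Prg3, Slc2a1 and Csf1r did not pass without control array 1 or without control array 3, Gusb and Col1a2 without control array 1, and Ms4a1 and Cmpk2 without control array 3. Without mimic array 2, members passed in the interferon (2), dendritic (4), NF-kB (2), monocyte (2), T and NK cell (2), stroma (1) and stress (1) lists and in no other. In limma's fry, which asks whether the genes of a list move on balance 1 way, 14 lists passed.

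The arrays' own control probe sets were compared between the groups. The 3′ actin control lay at 9.89 ± 0.42 in control and 8.96 ± 0.02 with the mimic (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). The middle and 5′ actin controls differed by -1.27 and -1.13 on the log2 scale, and the 3′ Gapdh control by -0.18. The 3′ minus 5′ difference of actin, a sign of RNA integrity, was 1.75 ± 0.09 in control and 1.96 ± 0.39 with the mimic (exact permutation p = 0.5), with mimic array 2 at 2.39. That of Gapdh was 0.31 ± 0.05 and 0.44 ± 0.34 (exact permutation p = 1), with mimic array 2 at 0.83 and the other 5 arrays between 0.24 and 0.37. Without mimic array 2 the group differences went from 0.21 to -0.01 for actin and from 0.13 to -0.07 for Gapdh. The bacterial spike-ins, which follow labelling and hybridisation, averaged 8.31, 7.31 and 7.26 in control arrays 1, 2 and 3 and 7.92, 7.79 and 8.66 in mimic arrays 1, 2 and 3 (exact permutation p = 0.3). The first principal component held 54.4% of the variance and placed control arrays 1, 2 and 3 at -38.1, -12.4 and -6.2 and the mimic arrays between 16.0 and 21.0.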

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

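Of the tests given here, those with the spike-in level as a covariate, the count without control array 1 and both correlations involving control array 1 were chosen only after the result was seen. The splits, the check of dendritic genes for cell composition and both tests of the published targets were written beforehand, but the width of the target intervals and the brighter targets were added to the latter only after the result was seen. The count without control array 1 took the place of an earlier criterion, the interferon median without that array, whose value of 0.81 had left the question undecided.

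Outside the gene tests, some probe sets with several gene symbols or none differed between the groups. In a fit of all 45037 probe sets, 404 passed an adjusted p of 0.05 by limma, and 43 of these had no single listed gene, with 22 higher and 21 lower with the mimic. This was 0.426% of the probe sets without a single gene, against 1.03% of those with 1 gene.

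Of the 10 splits of the 6 arrays into groups of 3, only the real grouping into mimic and control gave as many as 503 genes (highest of the others 0). The other splits mix mimic and control arrays, so the mimic difference widens their spread and a low count of genes adds little. Only the real grouping gave as many as 16 lists past camera, but control arrays 1 and 3 with mimic array 1 against the rest gave 12. A pass by camera at its preset correlation is therefore weak support by itself. The splits are too few for a share under 0.05.

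The interferon genes were higher and the dendritic and MHC class II genes lower with the mimic, by medians of 0.98 and -0.86 on the log2 scale. With the spike-in level as a covariate the medians were larger in size, at 1.16 over 23 interferon genes and -1.08 over 28 dendritic and class II genes. This cannot decide on the labelling level of the arrays as a cause. Control array 1, with the highest spike-in level of the controls (8.31), also had their lowest interferon median (-0.33 relative to the control mean). A larger difference with the covariate therefore followed largely from values already seen. Without control array 1, 12 of the 23 interferon genes rose and 1 fell, with a median of 0.81, so not all calls rest on that array. How much of the rise that array adds stays open, since this count replaced an undecided criterion after the result was seen. However, 2 rose without mimic array 2 and 0 without control array 2, mimic array 1 or mimic array 3, where the list medians were 0.93, 0.94, 1.01 and 0.99. The count without control array 1 did not cover the dendritic and class II genes, whose median without that array was -0.65. A smaller share of dendritic-like cells stays open for the fall, since 13 of 15 dendritic genes with a control mean of at least 3 were lower but spread over a range of 4.85 on the log2 scale, and the design has no measure of cell shares. Choosing genes by their control mean can favour falls. Without that choice 16 of the 19 measured dendritic genes were lower. A response to the mimic sequence, or to the mimic as a double-stranded RNA that differs from the control oligonucleotide, may each underlie the rise and stay open as untested, since each group had 1 oligonucleotide.

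Control array 1 lay beyond the other controls on the first principal component, at -38.1 against -12.4 and -6.2, and limma's array weights gave it 0.327 against 1.84 and 1.41 for the other controls and 1.80, 0.988 and 0.661 for mimic arrays 1, 2 and 3. Across 7662 genes, which are not independent replicates, the difference of control array 1 from control array 2 correlated at r = 0.344 with that of mimic array 3 from mimic array 1, where control array 1 and mimic array 3 have the highest spike-in levels of their groups (8.31 and 8.66). This goes with labelling level as a candidate explanation for part of the difference. Whether control array 1 also lacks part of what the mimic arrays show stays open, since its difference from control array 2 correlated at r = -0.252 with that of mimic array 1 from control array 3. No biological explanation for this array was tested, since the labels name no difference between the control arrays.

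None of 28 measured published targets of miR-142-3p passed the test among all genes. The 95% interval excluded a fall of 0.5 on the log2 scale for 23 of the 28. This argues against larger falls only for those of the 23 that lie clear of the floor, since a gene near it could not show such a fall. The bound was too wide for smaller falls, which stay open, since the median half-width of the intervals was 0.277 and the method recovered 29.0% of simulated changes of 0.5. The 25 with a mean log2 of at least 3 had a median log2 fold change of 0.0353, but that bound looked at 1 cutoff, and the floor of the array stays open, since the median was -0.12 over the 9 with at least 5 and -0.17 over the 4 with at least 7. Under 6 other settings 1 to 4 targets passed over all genes, each upward, with 4 under the spike-in covariate, and with dim genes left out Il6st or Bclaf1 passed upward and Rac1 downward (-0.31). The time of 4 days after transfection, control of translation without a change in RNA, the high level of miR-142-3p that marrow cells may already hold, and uptake of the mimic by few cells stay open as untested explanations.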

How the results depend on the processing

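The lower filters on dim genes (mean log2 below 1 or 3), the fit without control array 1 and mimic array 3 together, and the spike-in covariate were chosen after seeing the data. The seed site comparison and its alternatives were not run, since 3′ UTR sequences were not used here. Where a value moved, the cause was not tested, except that fits with fewer arrays or genes hold less information by construction. Dim genes are limited by the floor of the arrays, with 52.6% of values below 1.

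Against 503 changed genes (213 higher, 290 lower), the block on replicate number gave 314 (126 higher, 188 lower). The labels do not say whether the numbers pair the arrays. Deviations from the group means correlated at -0.13, 0.34 and -0.30 for numbers 1, 2 and 3, and not every array correlated best with its own number. These values do not show pairing, but with 3 arrays per group they cannot exclude it. Genes below a mean log2 of 7 left out gave 229 (112, 117), array weights 1047 (456, 591), the spike-in covariate 2026 (1135, 891) and a minimum fold of 1.2 gave 108 (38, 70). A trended robust variance gave 320 higher and repeated quantile normalisation 322 higher. With control array 1 and mimic array 3 both left out 0 genes passed by limma (0 higher, 0 lower; 3255 at an unadjusted p under 0.05). With 1 array left out the count ran from 0 to 413, with 0 to 165 higher and 0 to 248 lower: it was 0 without control array 2, mimic array 1 or mimic array 3, 65 without mimic array 2 and 356 without control array 1. Over the named genes, 828 of 1158 alternative values kept direction and side of the threshold, 303 lost and 25 gained the call, and 2 reversed: Lss at 0.0192 without probe sets of type _x_at or _s_at, and Il6st at -0.0284 with probe sets averaged. With control array 1 and mimic array 3 both left out, Ifit1bl1, Iigp1, Ifit2, Ccl22 and Arg1 stood at log2 fold changes of 4.09, 2.34, 1.75, -2.82 and 0.75, and Ifit1bl1 stood at 4.38 with array weights and 5.94 with the spike-in covariate.

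Of 26 lists, 16 passed. With genes below a mean log2 of 5 left out, 8 of the 19 lists that kept at least 3 members passed, and below 7, 5 of 14. Of the 16, 5 and 8 were not tested there and 3 were lost in each, and below 3 the stroma list was not tested. With an estimated correlation 0 of 26 passed, where the adjusted p was 0.161 for the interferon, dendritic, class II, NF-kB, IL-6, neutrophil precursor, monocyte, stem cell, mast cell, eosinophil and glycolysis lists, 0.223 for B cells, 0.24 for cholesterol, 0.322 for stroma, 0.37 for megakaryocytes and 0.481 for lysosomes. Other losses, as adjusted p, were these. With fry, B cells 0.0661, megakaryocytes 0.187, stroma 0.103, lysosomes 0.215 and cholesterol 0.0676. With probe sets averaged, B cells and lysosomes 0.111, stroma 0.0572 and cholesterol 0.057. Without probe sets of type _x_at or _s_at, B cells and lysosomes 0.0794 and glycolysis 0.0737. Without genes below 1, B cells and glycolysis 0.0882, and below 3, stem cells 0.0668, B cells 0.0591 and glycolysis 0.125. Without genes below 5, monocytes 0.0651, lysosomes 0.0505 and cholesterol 0.108, and below 7, NF-kB 0.166, lysosomes 0.0801 and monocytes 0.414, the last with the direction reversed. With the spike-in covariate, megakaryocytes 0.0698, stroma 0.198 and glycolysis 0.238. For lysosomes, array weights gave 0.133, quantile normalisation 0.0681 and the 2 arrays left out 0.0971. With 1 array left out, the adjusted p ran from 0.0134 to 0.115 for B cells, 0.00741 to 0.114 for glycolysis, 0.011 to 0.223 for lysosomes and 0.00604 to 0.221 for stroma. The block changed no call of a list. As a set the published targets passed under no alternative (adjusted p from 0.0714 with the spike-in covariate to 0.97 with array weights), and their direction went both ways. For the lists that did not pass, 11 of 202 alternative values did, in the p53, suppressor, mature neutrophil and erythroid lists. Among these, limma's fry passed the suppressor list (adjusted p = 4.44e-04) and the p53 list (adjusted p = 0.024) downward and the erythroid list upward (adjusted p = 0.024).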

Other observations

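Lists of class I presentation, interferon-inducible GTPases, schlafen genes, Fc receptors, lipid genes and actin cytoskeleton genes were put together after the main results were seen, and the class I and actin lists were adjusted over these 6. Camera was then run on the last 5 without the members whose values had been seen beforehand (adjusted over these 5), a test chosen after the result was seen. The test of the actin list was chosen only after the actin control probe sets were seen to be lower, while the prediction for the class I list was written before its result.

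The interferon-inducible GTPases, which attack the vacuoles of intracellular pathogens, rose in all 10 measured members over all genes tested. Gbp2, Gbp3, Gbp6, Gbp8 and Iigp1 had been seen to rise before the list was made. The other 5, Gbp7, Irgm1, Irgm2, Igtp and Ifi47, had a median log2 fold change of 1.27 (adjusted p = 1.07e-07 by limma's camera, adjusted p = 0.148 with an estimated correlation). Gbp8 rose by a log2 fold change of 2.30 ± 0.30, Gbp3 by 1.98 ± 0.39 and Igtp by 1.36 ± 0.19 (SE). Of 5 Fc receptor genes 2 rose, Fcgr4 (1.94 ± 0.26) and Fcgr1 (0.84 ± 0.11), both seen before the list was made, while Fcgr3 stood at 0.10 ± 0.09 (adjusted p = 0.644 by limma). Of 7 schlafen genes, a family induced by interferon, 1 rose, Slfn8 (1.2 ± 0.12), also seen before. Without these, the 3 other Fc receptor genes did not pass camera (adjusted p = 0.285), and the 6 other schlafen genes passed upward with a median of 0.32 and no member past the test (adjusted p = 0.0248, adjusted p = 0.341 with an estimated correlation).

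Genes regulated by the sterol receptor LXR and of fatty acid synthesis were lower in 10 of 11 members, of which 3 fell. The cholesterol exporter gene Abca1 and the stearoyl-CoA desaturase genes Scd1 and Scd2 fell, with log2 fold changes of -1.93 ± 0.27, -1.93 ± 0.31 and -1.41 ± 0.18 (SE). Abca1 and Scd1 had been seen before the list was made. The other 9 genes had a median of -0.27 (adjusted p = 0.00186 by limma's camera, adjusted p = 0.217 with an estimated correlation). Scd2 went from 8.17 ± 0.39 to 6.76 ± 0.02 (SD, n = 3).

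MHC class II genes were lower, and class I presentation genes were tested on the hypothesis that they move with the interferon genes. Of 13 measured members 12 had a higher mean and 4 rose, Nlrc5 (0.85 ± 0.11), the class I transactivator gene, Psmb10 (0.55 ± 0.09), Tap1 (0.52 ± 0.09) and Psmb9 (0.47 ± 0.09). The list passed camera upward (median log2 fold change 0.31, adjusted p = 1.79e-07), and with an estimated correlation its adjusted p was 0.0655.

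The actin control probe sets were lower with the mimic, and a candidate explanation is a fall of actin cytoskeleton genes together. Of 25 such genes 19 had a lower mean and 4 fell, Acta2 (-0.85 ± 0.12), Tpm4 (-0.73 ± 0.13), Tagln (-0.72 ± 0.11) and Actn1 (-0.68 ± 0.13). The list passed camera downward (median log2 fold change -0.23, adjusted p = 6.89e-06), and with an estimated correlation its adjusted p was 0.0655. Without Actb the other 24 passed too (adjusted p = 3.4e-05, adjusted p = 0.148 with an estimated correlation). Actb itself is in the list and did not pass (-1.13 ± 0.24, adjusted p = 0.0566 by limma), and its other probe set had a log2 fold change of 0.87, while Actg1 stood at -0.15 ± 0.08.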
